A study of Mus musculus with 26 samples.

How the data were processed

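The series holds 26 Affymetrix mouse expression arrays, 1 per sample, from 8 populations. The labels give 5 arrays for MPPFL- and 3 for each of MPPFL+, CMP, GMP, CLP, DN1, DN2 and DN3. They give bone marrow as the tissue, or thymocytes for DN1 to DN3, with C57/Bl6 males aged 2 months as donors. Groups were taken from the population named in each title with its replicate number. For MPPFL- and MPPFL+ another label spells the name MMPFL, and for CLP it reads ALP. Per the labels, RNA was taken up in Trizol and labelled with biotin by the array maker's protocol. The table holds values on a log2 scale as deposited by the authors. The way they were normalized and summarized per probe set is not given in the sources used here. The scale was checked on the table, where values ran up to 17.1, array medians lay between 2.74 and 3.05, and a single lowest value recurred on every array. That value was taken by 30.2% to 37.1% of the probe sets per array and is read as the floor of the measurement. Levels near it carry little information on expression, and the number of arrays limits precision elsewhere.

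Of 45101 probe sets, 34958 were named with 1 gene, 932 with several and 9211 with none, and 64 of the table were controls of the array maker. For 34754 of those named with 1 gene, the gene ID was found in a mouse gene table, and 0 symbols changed through that match. For each gene the probe set with the highest mean over all arrays was used, among probe sets named with 1 gene, which gave 18194 genes. Of these, 9012 had over 1 probe set and 1260 were at the floor on all arrays. The values were used as deposited, with no further normalization and no filter on dim genes.

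All arrays were fitted together with limma (version 3.58.1, R 4.3.3) by lmFit and eBayes, with population as the only term, 18 residual degrees of freedom and 0.553 prior degrees of freedom. Of all genes, those with a Benjamini-Hochberg adjusted p under 0.05 in a comparison, two-sided, are said to have passed, risen or fallen. The 8 comparisons were MPPFL+ with MPPFL-, CMP and CLP each with MPPFL+, GMP with CMP, DN1 with CLP, DN2 with DN1, DN3 with DN2, and CLP with GMP. Comparisons, tests, gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. Similarity was measured as the Pearson correlation between arrays over all genes. Fold changes against a population at the floor on all of its arrays are given as lower bounds, from the means of both. They are bounds with regard to the floor only and leave out the sampling error of the means. After the data had been seen, the same was done where all arrays of the lower population lay within 1 log2 unit of the floor, or shared a single low value to within 0.1.

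Genes were tested in 16 lists drawn up from general knowledge of blood cell formation. They were stem and early progenitor, granulocyte-macrophage, late neutrophil granule, erythroid and megakaryocyte, mast cell with basophil and eosinophil, early lymphoid, B lineage, T lineage, Notch target, late thymocyte, NK and innate lymphoid, dendritic cell and macrophage, stroma with epithelium and endothelium, cell cycle, DNA methylation, and immediate early and stress genes. Lists with at least 5 measured genes were tested with camera of limma, with a preset correlation between genes of 0.01, and adjusted over all 128 pairs of list and comparison. Of these pairs 56 passed, and 31 of the 56 also passed with a correlation estimated from the data. In 0 of the 56 did the median, the mean and the test differ in sign. A median of 0, as for the NK and innate lymphoid list in CMP with MPPFL+ (mean 0.605), did not count as a difference. The dendritic cell and macrophage list (20 measured genes), the stroma list (18) and the DNA methylation list (20) passed in none of the comparisons. The NK and innate lymphoid list passed for CMP with MPPFL+ alone and the late thymocyte list for CLP with GMP alone, and neither call held with an estimated correlation (adjusted p = 0.123 and 0.0908). Members not measured by a probe set of 1 gene were left out, and their names are not reported here.

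Genes are named in the text by a rule with 4 parts. The first takes, in each comparison, up to 6 genes with the largest rise and 6 with the largest fall among those that passed. Their arrays in the 2 populations must not overlap and their mean in the higher population must reach the median over genes of the mean of all arrays, which was 5.31. Genes without an assigned name are passed over. The second takes up to 3 members of each list described, those that passed with the largest change. The third takes Dnmt1, Dnmt3a, Dnmt3b, Dnmt3l, Uhrf1, Tet1, Tet2 and Tet3 in every comparison, and Flt3 in MPPFL+ with MPPFL-, whatever their test. The last takes Flt3, Il7r, Mpo, Il2ra and Kit in every population as a check of the labels. The text names only part of the genes that the rule allows. Xist and Eif2s3y fall outside the rule and were chosen after their values were seen.

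Recovery was tested on simulated data, with changes added to 50 genes at each of 4 sizes and the fit repeated for the 18194 genes of CLP with MPPFL+. Of each 50, the test found 5 at 1.5-fold, 23 at 2-fold, 44 at 4-fold and 49 at 8-fold. In all 131 genes passed, of which 10 had not been changed. The changed genes were drawn from those at or above the median level, so recovery of dim genes was not tested. No other genes differed between the simulated populations, while 1190 genes passed in the data, so the adjustment of p differs.

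The alternatives were quantile normalization between arrays, leaving out dim genes, the mean of all probe sets of a gene, every probe set tested, only the 2 populations compared in the fit, eBayes with trend and robust variance, a further threshold of 2-fold, replicate number as a block, leaving out each array in turn, and MPPFL- in place of MPPFL+ as reference. For lists, an estimated correlation was used, and for similarity, Spearman correlation and only the most variable genes. After the data had been seen, further alternatives were added. These were leaving out genes at the floor on all arrays, the spike-in cluster as a random block or only the arrays of a shared cluster, the spike-in subclusters as a block, the difference of the Gapdh 3' and 5' control probe sets as a covariate, and leaving out DN1 replicate 3 and DN2 replicate 2. The spike-in clusters came from hierarchical clustering of 24 poly-A and 18 hybridisation control probe sets. Ranges of adjusted p over alternatives cover only those run for lists or for named genes. Fits with every probe set, with only the 2 populations compared or with spike-in clusters or subclusters were run for neither. Trend and robust variance was not run for lists. Methylation data of the series title were not used here.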

Results

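Messenger RNA was measured on 26 Affymetrix arrays, 1 array per sample, from 8 blood cell progenitor populations of C57/Bl6 mice aged 2 months. Bone marrow gave the MPPFL- population (n = 5) and the MPPFL+, CMP, GMP and CLP populations (n = 3 each). Thymocytes gave the DN1, DN2 and DN3 populations (n = 3 each). In the usual names of the field, MPP are multipotent progenitors, CMP common myeloid progenitors, GMP granulocyte-macrophage progenitors, CLP common lymphoid progenitors, and DN1 to DN3 successive early thymocyte stages. The titles call the CLP arrays CLP, and another label of the same arrays reads ALP. The labels do not say that replicates came from separate animals, so the p-values below measure only the spread between these samples. The arrays reported 45101 probe sets on a log2 scale. A common lowest value was taken by 30.2% to 37.1% of the probe sets on each array. Array medians lay between 2.74 and 3.05, and 18194 genes were tested.

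Levels of 5 genes that mark some of these populations were set against the labels. Flt3, the cytokine receptor that the FL of the MPP names is read as here, was at 13.31 ± 0.29 on the log2 scale in MPPFL+ (SD, n = 3) and at 10.995 ± 0.39 in MPPFL- (SD, n = 5). It was at 13.58 ± 0.02 in CLP and at 4.90 ± 0.53 in GMP (SD, n = 3). Il7r, the interleukin 7 receptor of lymphoid progenitors, was at 13.23 ± 0.06 in CLP and at 4.81 ± 2.38 in MPPFL+. Mpo, the myeloperoxidase of granule-forming cells, had its highest mean in GMP, 16.11 ± 0.03, and its lowest in DN3, 3.82 ± 2.20, but was also high in lymphoid populations, at 14.15 in CLP, 13.59 in DN1 and 11.31 in DN2. Il2ra, the surface protein CD25 that appears on early thymocytes, was at the lowest value on all arrays of MPPFL-, MPPFL+, GMP and CLP and at 2.19 ± 0.03 in CMP. It was at 7.37 ± 1.04 in DN1, 13.14 ± 0.45 in DN2 and 13.16 ± 0.35 in DN3. Kit, the stem cell factor receptor, was at 11.96 ± 0.25 in DN1, 11.66 ± 0.21 in DN2 and 9.95 ± 0.20 in DN3.

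**Figure D1:**
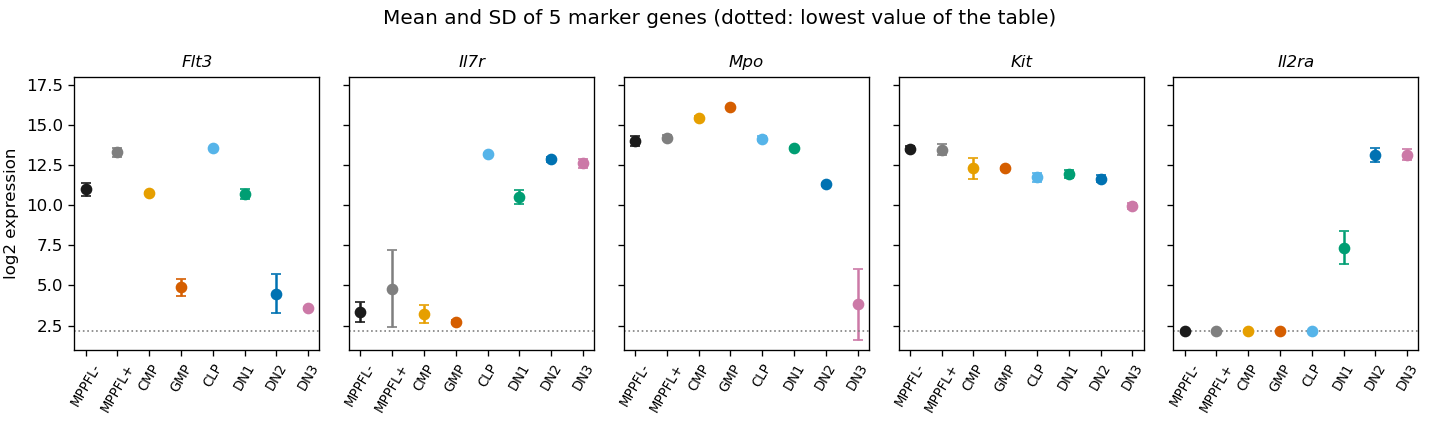
Mean log2 expression of 5 marker genes in the 8 populations, with bars of 1 SD (n = 5 in MPPFL-, n = 3 elsewhere) and a dotted line at the lowest value of the table. Il2ra leaves that line in DN1, DN2 and DN3, and Il7r is at 13.23 in CLP.

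Every array was most similar to another array of its own population, in 26 of 26 cases by Pearson correlation across genes, which are not independent replicates. Correlations within a population were lowest in CMP, where the lowest was 0.979, and reached 0.998 in MPPFL- and GMP. Between population means, MPPFL+ and CLP correlated at 0.987 and DN1 and DN2 at 0.987, while GMP and DN3 correlated at 0.910. The first principal component held 32.7% of the variance and the second 22.3%.

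**Figure D2:**
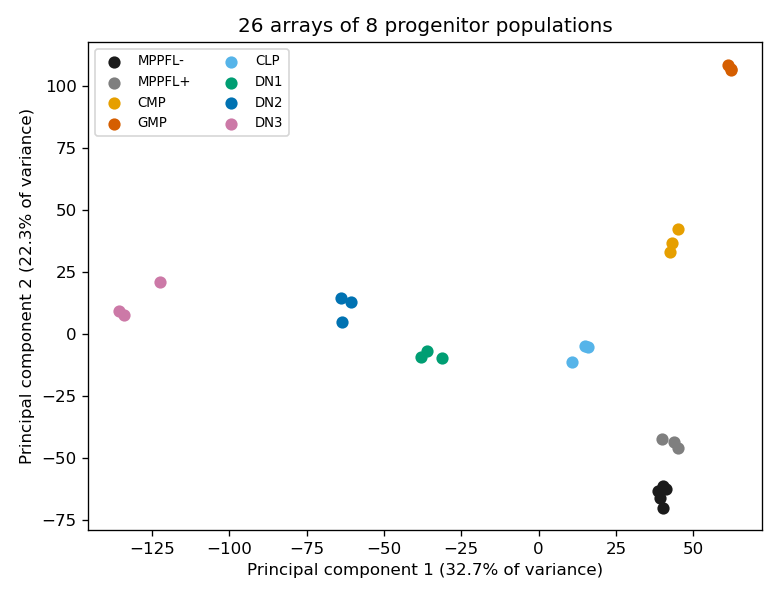
The 26 arrays on the first 2 principal components of all genes, 1 point per array, coloured by population. The DN3 arrays lie at the left end of the first component and the GMP arrays at the top of the second.

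Control and sex-linked probe sets set some arrays apart. The mean of the poly-A spike-in controls, which are added to the RNA before labelling, was 4.60 ± 0.48 in MPPFL- (SD, n = 5), 4.48 ± 0.85 in MPPFL+ and 4.42 ± 0.23 in CLP (SD, n = 3). It was 9.86 ± 0.43 in CMP, 8.05 ± 0.17 in GMP and 12.09 ± 1.10 in DN3, and near the lowest value in DN1 and DN2, at 2.56 ± 0.04 and 2.54 ± 0.04. Clustering the arrays on their spike-in controls, a step chosen after seeing the data, gave 6 clusters. These were MPPFL- with MPPFL+ and CLP, CMP replicate 1 alone, CMP replicates 2 and 3 with DN3 replicate 3, GMP, DN1 with DN2, and DN3 replicates 1 and 2. The list of immediate early and stress genes, which respond to cell handling, had its highest population mean in DN1, 11.64 ± 1.16, followed by DN2 at 9.97 ± 1.44 and CMP at 9.71 ± 0.27. It was at 9.07 on DN3 replicate 3 against 7.05 and 7.19 on the other DN3 arrays. All arrays are labelled male. Xist, the RNA of the inactive X chromosome in females, was at 12.21 on DN1 replicate 1, 13.59 on DN1 replicate 3, 12.99 on DN2 replicate 2 and 6.30 on DN2 replicate 3, and Y-linked Eif2s3y was at 2.62 on DN1 replicate 3 and at the lowest value on DN2 replicate 2.

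**Figure D3:**
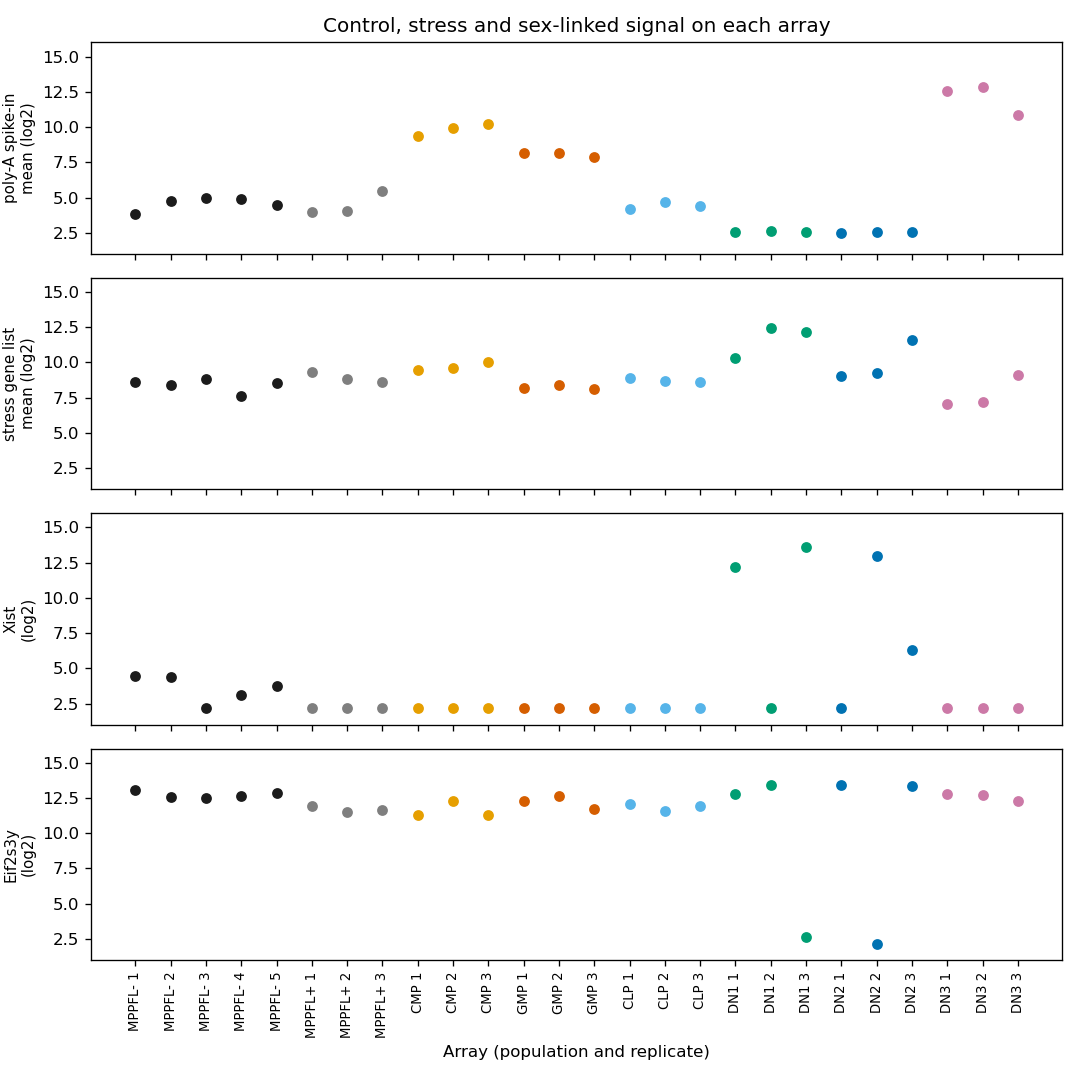
Poly-A spike-in mean, mean of the immediate early and stress gene list, Xist and Eif2s3y on each array, all in log2 units, 1 point per array, coloured by population. Eif2s3y is at 2.62 on DN1 replicate 3 and at the lowest value on DN2 replicate 2, where Xist is at 13.59 and 12.99.

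The comparison of MPPFL+ with MPPFL- addresses what separates multipotent progenitors by their FL label. Early lymphoid genes were higher in MPPFL+. Ccr9, a chemokine receptor that guides progenitors to the thymus, was at 8.92 ± 0.58 in MPPFL+ (SD, n = 3) and 2.56 ± 0.31 in MPPFL- (SD, n = 5), near the floor, and so was at least 81.9-fold higher (adjusted p = 4.36e-08). Of the MPPFL- arrays, replicate 4 was at 3.09 and the others lay between 2.33 and 2.53. Here and below, "at least" refers to the floor in the lower population and not to the spread between arrays. Dntt, which adds nucleotides to antigen receptor gene joints, rose by 5.23 (SE 0.21, adjusted p = 5.42e-12), and Ighm, the immunoglobulin mu heavy chain, by 4.69 (SE 0.25, adjusted p = 3.41e-10). Of their other probe sets, 2 of 2 passed in the same direction for Dntt, but only 1 of 10 for Ighm and 1 of 4 for Ccr9. In each case 0 passed in the opposite direction. Notch1, the receptor that directs T lineage entry, rose by 2.39 (SE 0.25, adjusted p = 2.05e-06) and Flt3 by 2.32 (SE 0.36, adjusted p = 0.000148). Stem cell and megakaryocyte genes were lower in MPPFL+. Aldh1a1, an aldehyde dehydrogenase, fell by 6.38 on the log2 scale (SE 0.36, adjusted p = 6.47e-10) and Tek, the angiopoietin receptor of stem cells and endothelium, fell by 4.48 on the log2 scale (SE 0.23, adjusted p = 2.56e-10). Gata1, the master transcription factor of red cells and megakaryocytes, fell by 4.45 on the log2 scale (SE 0.36, adjusted p = 6.28e-08), and Cavin2, a caveola protein, was at the lowest value on all MPPFL+ arrays and at least 45.5-fold lower than in MPPFL- (adjusted p = 2.36e-09).

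Of 17 measured early lymphoid genes, 11 rose and 1 fell in MPPFL+ (13 and 1 adjusted over the list alone), with a median log2 fold change of 1.46 (list adjusted p = 9.04e-11). Of 27 stem and early progenitor genes, 1 rose and 13 fell (1 and 17 adjusted over the list alone; list adjusted p = 9.04e-11), and of 27 erythroid and megakaryocyte genes 1 rose and 11 fell (1 and 13 adjusted over the list alone; list adjusted p = 1.46e-10). Cell cycle genes rose in 14 of 29 cases and fell in 0 (15 and 0 adjusted over the list alone; list adjusted p = 5.64e-07), among them the mitotic kinases Plk1, by 1.83 (SE 0.31, adjusted p = 0.000355), and Aurka, by 1.66 (SE 0.28, adjusted p = 0.00029). The mast cell, basophil and eosinophil list passed with 3 of 14 genes lower and 0 higher (list adjusted p = 0.0162), but not with an estimated correlation (adjusted p = 0.22 with an estimated correlation). The B lineage list, with 4 of 23 genes higher and 0 lower (list adjusted p = 0.0297), was lost in the same way (adjusted p = 0.256 with an estimated correlation) and with the difference of 3' to 5' control signal in the fit (0.064). Over the alternatives run for lists its adjusted p ran from 0.0147 to 0.256. Over all genes, 1930 were higher and 955 lower in MPPFL+, 2885 in all. With every probe set tested, 3406 were higher and 3354 lower. Without MPPFL+ replicate 2 the count was 1898. Both populations lay in 1 spike-in cluster, and a fit to the arrays of that cluster alone gave 3538. They differed without overlap in 2 other control measures. The ribosomal RNA control signal was 14.15 ± 0.15 in MPPFL- (SD, n = 5) and 12.81 ± 0.29 in MPPFL+ (SD, n = 3), and the actin 3' signal exceeded the 5' signal by 3.74 ± 0.38 and 2.74 ± 0.19. Among 940 genes with at least 2 probe sets passing the test, 225 had probe sets that moved in opposite directions.

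**Figure D4:**
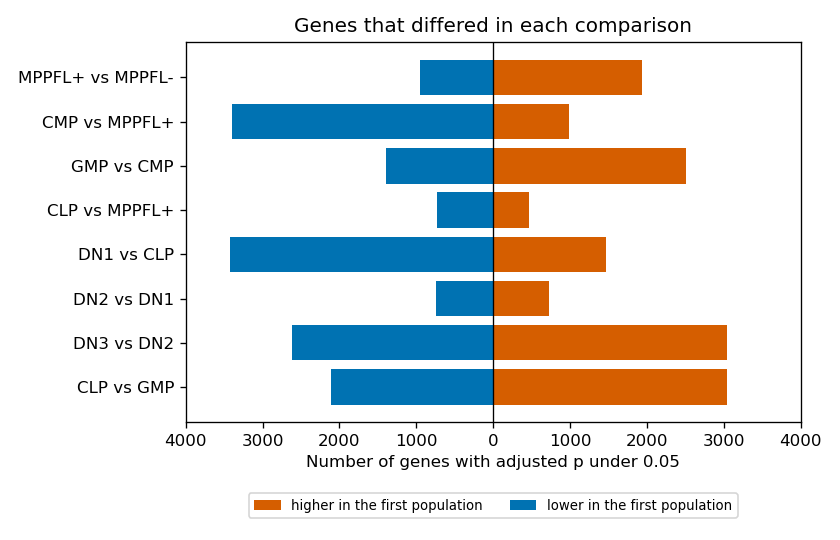
Number of genes with adjusted p under 0.05 in each of the 8 comparisons, higher in the first-named population to the right and lower to the left. The total is smallest in CLP against MPPFL+, with 461 higher and 729 lower, and largest in DN3 against DN2, with 3039 and 2613.

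The comparison of CMP with MPPFL+ concerns the first myeloid step. Red cell, megakaryocyte and mast cell genes were higher in CMP. Gata1 was at 10.98 ± 0.12 in CMP and 4.07 ± 0.34 in MPPFL+ (SD, n = 3), a rise of 6.91 (SE 0.40, adjusted p = 2.68e-10). Ms4a2, a chain of the IgE receptor of mast cells and basophils, was at least 105-fold higher (adjusted p = 9.48e-12), and Mfsd2b, a sphingosine-1-phosphate transporter of red cells and platelets, at least 250-fold higher (adjusted p = 1.44e-12). Among granulocyte and macrophage genes, the plasma protein gene Hp rose by 6.73 (SE 0.35, adjusted p = 5.6e-11) and Ms4a3 by 6.60 (SE 0.54, adjusted p = 4.27e-08). Stem cell and lymphoid genes were lower. Hlf, a transcription factor of stem cells, fell by 5.21 on the log2 scale (SE 0.28, adjusted p = 6.99e-11), and Procr, the protein C receptor that marks stem cells, fell by 5.16 on the log2 scale (SE 0.43, adjusted p = 5.17e-08). Ccr9 was at least 91.4-fold lower (adjusted p = 5.44e-08). Flt3 fell by 2.55 on the log2 scale (SE 0.40, adjusted p = 0.000108). The heat shock gene Hspa1a, a member of the stress list, was at least 123-fold higher by the means (adjusted p = 0.00115), although of 20 genes of that list only 3 rose and 0 fell (2 and 0 adjusted over the list alone) and the list did not pass. Hspa1a ran from 8.44 to 10.19 on the CMP arrays, so this fold is not a bound for each array.

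Of 27 erythroid and megakaryocyte genes, 20 rose and 1 fell in CMP (21 and 2 adjusted over the list alone; median log2 fold change 1.70, list adjusted p = 3.05e-20). Granulocyte-macrophage genes rose in 15 and fell in 2 of 26 cases (16 and 3 adjusted over the list alone; median 1.71, list adjusted p = 4.77e-13), and mast cell, basophil and eosinophil genes rose in 5 and fell in 0 of 14 (5 and 0 adjusted over the list alone; list adjusted p = 1.76e-06). Stem and early progenitor genes rose in 3 and fell in 16 of 27 cases (3 and 18 adjusted over the list alone; list adjusted p = 3.89e-06), and early lymphoid genes fell in 11 and rose in 0 of 17 (11 and 0 adjusted over the list alone; list adjusted p = 7.37e-06). The late neutrophil granule list passed with 4 of 13 genes higher (list adjusted p = 0.000125), but not with an estimated correlation (adjusted p = 0.166 with an estimated correlation). The NK and innate lymphoid list passed with 3 of 18 genes higher and 1 lower (list adjusted p = 0.022), but not with an estimated correlation (adjusted p = 0.123 with an estimated correlation), after quantile normalization (0.095) or with the mean of the probe sets of a gene (0.0733). Over the alternatives run for lists its adjusted p ran from 0.00551 to 0.123. Over all genes, 981 were higher and 3397 lower, 4378 in all. The number of higher genes rested on single arrays, with 1887 without CMP replicate 2 and 1754 without CMP replicate 3. Quantile normalization moved the share of higher genes from 22.4% to 36.4%, and the median change of the 10087 genes that were not dim by 0.22 on the log2 scale, from -0.34 to -0.12. The corresponding move was -0.12 for GMP against CMP, where the share of higher genes went from 64.3% to 55.7%. CMP and MPPFL+ lay in different spike-in clusters, and with the cluster as a random block 636 genes passed. The Gapdh 3' signal exceeded the 5' signal by 2.26 ± 0.35 in CMP and 3.07 ± 0.23 in MPPFL+, without overlap.

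The comparison of GMP with CMP concerns the second myeloid step. Granulocyte-macrophage genes were higher in GMP, as were single eosinophil genes. Prg2, the eosinophil granule major basic protein, was at 13.14 ± 0.25 in GMP and 2.91 ± 1.29 in CMP (SD, n = 3), a rise of 10.23 (SE 0.42, adjusted p = 8.15e-13), and Epx, the eosinophil peroxidase, was at least 359-fold higher (adjusted p = 4.22e-17). Fcnb, a ficolin of myeloid cells, was at least 74.1-fold higher (adjusted p = 5.7e-35), and Fcgr3, an IgG receptor, rose by 3.73 (SE 0.23, adjusted p = 2.86e-10). Lcn2, a neutrophil granule lipocalin, rose by 5.32 (SE 0.90, adjusted p = 0.000221). Red cell, stem cell and lymphoid genes were lower. Klf1, a red cell transcription factor, was at least 115-fold lower (adjusted p = 1.79e-11), and Mecom, a stem cell transcription factor, fell by 4.18 on the log2 scale (SE 0.26, adjusted p = 3.31e-10). Dntt was at least 506-fold lower (adjusted p = 3.29e-16). Flt3 fell by 5.87 on the log2 scale (SE 0.40, adjusted p = 1.87e-09). Mpo was high in both, at 16.11 ± 0.03 in GMP and 15.48 ± 0.10 in CMP, a difference of 0.64 that did not pass the test (SE 0.61, adjusted p = 0.567). That SE pools the spread of all populations, which for Mpo was largest in DN3 (SD 2.20).

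All erythroid and megakaryocyte genes that passed were lower in GMP, 21 of 27 with 0 higher (22 and 0 adjusted over the list alone; median log2 fold change -4.02, list adjusted p = 6.46e-23), as were 21 of 27 stem and early progenitor genes (21 adjusted over the list alone; median -1.73, list adjusted p = 1.63e-20). Granulocyte-macrophage genes rose in 18 and fell in 0 of 26 cases (19 and 0 adjusted over the list alone; median 1.14, list adjusted p = 5.09e-13), and early lymphoid genes fell in 8 and rose in 0 of 17 (8 and 0 adjusted over the list alone; list adjusted p = 1.72e-06). Late neutrophil granule genes rose in 5 and fell in 0 of 13 cases (8 and 0 adjusted over the list alone; list adjusted p = 2.69e-05), a call lost with an estimated correlation (adjusted p = 0.123 with an estimated correlation). Cell cycle genes rose in 12 and fell in 0 of 29 (13 and 0 adjusted over the list alone; list adjusted p = 0.000196), also lost (adjusted p = 0.12 with an estimated correlation). The stress list, high in CMP, fell in 6 and rose in 0 of 20 cases (list adjusted p = 0.00531), again not with an estimated correlation (adjusted p = 0.518 with an estimated correlation), and Hspa1a was at least 102-fold lower (adjusted p = 0.00176). The mast cell, basophil and eosinophil list (6 of 14 higher and 2 lower), the T lineage list (2 of 27 higher and 5 lower) and the Notch target list (0 of 13 higher and 4 lower) passed with the preset correlation but not with an estimated correlation (adjusted p = 0.257, 0.49 and 0.362 with an estimated correlation). The mast cell list was also lost without CMP replicate 2 (0.0925; range over alternatives 0.0049 to 0.257), as was the T lineage list (0.054; range 0.0213 to 0.49). The Notch target list was lost without CMP replicate 1 (0.167), GMP replicate 1 (0.0584) or GMP replicate 3 (0.0677; range 0.0306 to 0.362). Both of the latter lists were lost with quantile normalization (0.0763 and 0.0889) and the 3' to 5' covariate (0.0516 and 0.0668), and the Notch target list with the mean of the probe sets of a gene (0.0701). Over all genes, 2503 were higher and 1389 lower, 3892 in all. Without CMP replicate 2 there were 2775 and 2408. The populations lay in different spike-in clusters, and with the cluster as a random block 733 genes passed. The actin 3' signal exceeded the 5' signal by 1.49 ± 0.03 in GMP and 2.27 ± 0.64 in CMP, without overlap.

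The comparison of CLP with MPPFL+ concerns the first lymphoid step, between populations of 1 spike-in cluster. Early lymphoid and B lineage genes were higher in CLP. Il7r rose by 8.42 (SE 0.71, adjusted p = 9.25e-08). Blnk, an adaptor of B cell receptor signalling, was at 10.95 ± 0.10 in CLP and 4.99 ± 1.02 in MPPFL+ (SD, n = 3), a rise of 5.96 (SE 0.27, adjusted p = 1.24e-11). Rag1, which starts antigen receptor gene recombination, rose by 5.55 (SE 0.43, adjusted p = 2.29e-08). Ly6d, a surface protein of lymphoid progenitors turning to the B lineage, was at least 39.8-fold higher (adjusted p = 4.66e-13), and the transcription factor gene Irf8 rose by 3.67 (SE 0.37, adjusted p = 7.55e-07). Stem cell genes were lower. Procr fell by 7.20 on the log2 scale (SE 0.43, adjusted p = 6.4e-10), and Tgfbi, an extracellular matrix protein, fell by 7.13 on the log2 scale (SE 0.43, adjusted p = 7.13e-10). Fgd5, a stem cell marker, was at least 33.0-fold lower (adjusted p = 4.33e-12), as was Pf4, a platelet chemokine, at least 27.8-fold (adjusted p = 1.38e-08). Flt3, at 13.58 in CLP and 13.31 in MPPFL+, did not pass the test (difference 0.27, SE 0.40, adjusted p = 1).

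Of 27 stem and early progenitor genes, 18 fell and 0 rose in CLP (23 and 0 adjusted over the list alone; median log2 fold change -1.80, list adjusted p = 8.8e-37). Of 23 B lineage genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone; list adjusted p = 1.12e-13), and of 17 early lymphoid genes 8 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.51, list adjusted p = 4.42e-10). Erythroid and megakaryocyte genes fell in 6 and rose in 0 of 27 cases (7 and 0 adjusted over the list alone; list adjusted p = 4.44e-06), a call lost with an estimated correlation (adjusted p = 0.0615 with an estimated correlation). T lineage genes rose in 7 and fell in 2 of 27 (8 and 2 adjusted over the list alone; list adjusted p = 6.48e-05), also lost (adjusted p = 0.217 with an estimated correlation). The cell cycle list, with 1 gene higher, and the late neutrophil granule list, with 1 lower, were lost with an estimated correlation (adjusted p = 0.206 and 0.385 with an estimated correlation). The former was also lost without MPPFL+ replicate 2 (0.109; range over alternatives 0.000121 to 0.206) and the latter without MPPFL+ replicate 3 (0.524; range 0.000454 to 0.524). Over all genes, 461 were higher and 729 lower, 1190 in all, the smallest of the 8 counts. A fit to the arrays of the shared spike-in cluster alone gave 1309. With only these 2 populations in the fit, 596 passed.

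The comparison of DN1 with CLP sets the earliest thymocyte stage against the lymphoid progenitor of the bone marrow, so that tissue and population change together. Notch targets were higher in DN1, while of the T lineage genes as many fell as rose. Hes1, a target of Notch signalling, was at 10.25 ± 0.69 in DN1 and 4.62 ± 0.33 in CLP (SD, n = 3), a rise of 5.63 (SE 0.32, adjusted p = 2.71e-10). Gata3, a T lineage transcription factor, rose by 3.86 (SE 0.31, adjusted p = 3.1e-08), Trat1, an adaptor of the T cell receptor, was at least 53.1-fold higher (adjusted p = 2.4e-16), and Il2ra at least 36.7-fold higher (adjusted p = 6.84e-10). Fasl, a death receptor ligand, was at the lowest value on all CLP arrays and at least 624-fold higher in DN1 (adjusted p = 1.82e-18). Several B lineage genes were lower. Blnk was at the lowest value on all DN1 arrays, at least 440-fold lower than in CLP (adjusted p = 3.68e-14), and Ebf1, a B lineage transcription factor, was at least 20.6-fold lower (adjusted p = 4.97e-08). Irf8 fell by 6.20 on the log2 scale (SE 0.37, adjusted p = 4.56e-10), and Aurkb, a mitotic kinase, fell by 2.75 on the log2 scale (SE 0.22, adjusted p = 1.99e-08).

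Of 13 Notch targets, 7 rose and 1 fell in DN1 (7 and 1 adjusted over the list alone; median log2 fold change 1.09, list adjusted p = 8.16e-08). Of 29 cell cycle genes, 20 fell and 0 rose (22 and 0 adjusted over the list alone; median -1.04, list adjusted p = 2.92e-08). Stress genes rose in 13 and fell in 0 of 20 cases (14 and 0 adjusted over the list alone; median 2.56, list adjusted p = 2.19e-09), a call lost with an estimated correlation (adjusted p = 0.166 with an estimated correlation). Among them, Nr4a1 rose by 5.74 (SE 0.90, adjusted p = 7.11e-05) and Hspa1a by 8.17 (SE 1.41, adjusted p = 0.000194). The B lineage list fell in 10 and rose in 1 of 23 cases (list adjusted p = 0.00339), but not with an estimated correlation (adjusted p = 0.123 with an estimated correlation) or without dim genes (0.137; range over alternatives 0.000277 to 0.137). T lineage genes rose in 6 and fell in 6 of 27 cases (8 and 6 adjusted over the list alone; list adjusted p = 0.0217). This call was lost with an estimated correlation (adjusted p = 0.481 with an estimated correlation) and without DN1 replicate 1 (0.159; range over alternatives 0.00314 to 0.481). Over all genes, 1461 were higher and 3429 lower, 4890 in all. With every probe set tested, 4578 were higher and 5855 lower. DN1 and CLP lay in different spike-in clusters, Xist was high on DN1 replicates 1 and 3, and the ribosomal RNA control signal was 9.67 ± 1.87 in DN1 and 12.93 ± 0.14 in CLP. With the cluster as a random block 599 genes passed. In 520 of 1784 genes with at least 2 probe sets passing the test, the probe sets moved in opposite directions.

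The comparison of DN2 with DN1 concerns the step at which thymocytes commit to the T lineage, between populations of 1 spike-in cluster. T cell genes were higher in DN2. Bcl11b, the transcription factor of T lineage commitment, was at 13.91 ± 0.14 in DN2 and 5.60 ± 3.24 in DN1 (SD, n = 3), a rise of 8.32 (SE 0.96, adjusted p = 7.37e-06). That SE pools the spread of all populations and so understates the spread of Bcl11b in DN1. Cd3g, a chain of the T cell receptor complex, rose by 6.80 (SE 0.57, adjusted p = 1.2e-07) and Il2ra by 5.77 (SE 0.32, adjusted p = 3.51e-10). Myeloid and stem cell genes were lower. Csf1r, the receptor for macrophage colony-stimulating factor, fell by 7.28 on the log2 scale (SE 0.41, adjusted p = 4.73e-10), and Prtn3, a neutrophil granule protease, was at least 94.0-fold lower (adjusted p = 4.68e-12). Flt3 fell by 6.23 on the log2 scale (SE 0.40, adjusted p = 3.23e-09). Meis1, a stem cell transcription factor, fell by 4.47 on the log2 scale (SE 0.31, adjusted p = 6.55e-09), and Lmo2, a partner of Tal1 in progenitors, fell by 4.08 on the log2 scale (SE 0.21, adjusted p = 1.89e-10).

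Of 27 T lineage genes, 16 rose and 1 fell in DN2 (18 and 2 adjusted over the list alone; median log2 fold change 1.44, list adjusted p = 2.15e-18). Cell cycle genes rose in 16 and fell in 0 of 29 cases (24 and 0 adjusted over the list alone; median 0.91, list adjusted p = 8.19e-18), among them Aurkb by 1.63 (SE 0.22, adjusted p = 3.87e-05). Granulocyte-macrophage genes fell in 14 and rose in 1 of 26 (17 and 2 adjusted over the list alone; median -1.47, list adjusted p = 9.47e-16), and stem and early progenitor genes fell in 8 and rose in 1 of 27 (13 and 1 adjusted over the list alone; list adjusted p = 1.27e-09). Stress genes fell in 6 and rose in 0 of 20 (9 and 0 adjusted over the list alone; median -1.74, list adjusted p = 1.38e-07), a call lost with an estimated correlation (adjusted p = 0.225 with an estimated correlation). Over all genes, 726 were higher and 749 lower, 1475 in all. Without DN2 replicate 2 there were 481 and 571, and without DN1 replicate 3 there were 486 and 610. With only the arrays of these 2 populations, which are also all the arrays of their spike-in cluster, 273 passed. Without DN1 replicate 3 and DN2 replicate 2, which lacked Y-linked signal, 798 passed. The ribosomal RNA control signal was 7.92 ± 0.35 in DN2 and 9.67 ± 1.87 in DN1, without overlap.

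The comparison of DN3 with DN2 concerns the following thymocyte stage, where the pre-T cell receptor is assembled. Ptcra, the alpha chain of that receptor, was at 12.81 ± 0.47 in DN3 and 2.94 ± 0.43 in DN2 (SD, n = 3), a rise of 9.88 (SE 0.25, adjusted p = 1.88e-16). Lef1, a T lineage transcription factor, was at the lowest value on all DN2 arrays and at least 553-fold higher in DN3 (adjusted p = 2.06e-19). Rag1 rose by 5.74 (SE 0.43, adjusted p = 3.09e-09), and Dtx1, a Notch target, by 6.28 (SE 0.27, adjusted p = 8.11e-13). Progenitor genes were lower, as was Mpo. Cd34, a progenitor surface protein, was at least 346-fold lower (adjusted p = 5.13e-15). Hoxa9, a homeobox gene of stem cells, fell by 5.79 on the log2 scale (SE 0.19, adjusted p = 1.27e-14), and Tal1, a stem cell transcription factor, was at least 52.0-fold lower (adjusted p = 1.27e-14). Mpo fell by 7.49 on the log2 scale (SE 0.61, adjusted p = 1.04e-08). It was at 6.36 on DN3 replicate 3, without which it fell by 8.76 on the log2 scale. Mitotic genes were lower too. The spindle checkpoint kinase gene Ttk fell by 5.21 on the log2 scale (SE 0.29, adjusted p = 5.23e-11) and Plk1 fell by 5.13 on the log2 scale (SE 0.35, adjusted p = 7.88e-10).

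Of 29 cell cycle genes, 27 fell and 0 rose in DN3 (27 and 0 adjusted over the list alone; median log2 fold change -2.87, list adjusted p = 1.1e-22). T lineage genes rose in 22 and fell in 2 of 27 cases (22 and 2 adjusted over the list alone; median 2.28, list adjusted p = 2.73e-13), and stem and early progenitor genes fell in 13 and rose in 2 of 27 (14 and 2 adjusted over the list alone; list adjusted p = 8.73e-06). Calls of 3 further lists were lost with an estimated correlation. Notch targets rose in 7 and fell in 3 of 13 cases (list adjusted p = 0.0139; adjusted p = 0.256 with an estimated correlation). Granulocyte-macrophage genes fell in 9 and rose in 2 of 26 (list adjusted p = 0.0131; adjusted p = 0.174 with an estimated correlation). Early lymphoid genes rose in 8 and fell in 1 of 17 (list adjusted p = 0.0188; adjusted p = 0.276 with an estimated correlation), and this call was also lost without dim genes (0.0646; range over alternatives 0.00269 to 0.276). Stress genes fell in 10 and rose in 1 of 20 cases (11 and 2 adjusted over the list alone; list adjusted p = 0.0031), a call lost with an estimated correlation (adjusted p = 0.496 with an estimated correlation) and without DN2 replicate 3 (0.0751; range over alternatives 6.94e-05 to 0.496). Over all genes, 3039 were higher and 2613 lower, 5652 in all, the largest of the 8 counts. The DN3 arrays lay in 2 spike-in clusters apart from the cluster of DN2, and with the cluster as a random block 1790 genes passed. The ribosomal RNA control signal was 13.81 ± 0.32 in DN3 and 7.92 ± 0.35 in DN2. With only these 2 populations in the fit, 3694 passed.

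The comparison of CLP with GMP sets the lymphoid against the myeloid progenitor of the bone marrow. Dntt was at 14.06 ± 0.07 in CLP and 2.19 ± 0.02 in GMP (SD, n = 3), near the floor, and was at least 3727-fold higher in CLP (adjusted p = 2.39e-18). Il7r was at least 1461-fold higher in CLP (adjusted p = 7.15e-10), Rag1 at least 270-fold (adjusted p = 1.7e-11) and Blnk at least 440-fold (adjusted p = 4.72e-15), and Flt3 was higher by 8.68 (SE 0.40, adjusted p = 2.31e-12). Granule genes were lower in CLP. Ms4a3 was at least 2106-fold lower (adjusted p = 5.33e-12). Elane, the neutrophil elastase, differed by -10.31 (SE 0.77, adjusted p = 2.68e-09), and S100a8, a calcium-binding protein of neutrophils, by -10.22 (SE 1.01, adjusted p = 1.55e-07). Prg2 was at the lowest value on all CLP arrays and at least 2004-fold lower than in GMP (adjusted p = 1.45e-13).

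Early lymphoid genes were higher in CLP in 15 and lower in 0 of 17 cases (15 and 0 adjusted over the list alone; median log2 fold change 3.32, list adjusted p = 1.47e-16). B lineage genes were higher in 12 and lower in 0 of 23 (12 and 0 adjusted over the list alone; list adjusted p = 1.06e-07), and stem and early progenitor genes in 14 and 1 of 27 (15 and 2 adjusted over the list alone; list adjusted p = 3.44e-05). Lower in CLP were 20 of 26 granulocyte-macrophage genes, with 2 higher (21 and 2 adjusted over the list alone; median -2.68, list adjusted p = 2.57e-21). So were 12 of 13 late neutrophil granule genes, with 0 higher (12 and 0 adjusted over the list alone; median -5.44, list adjusted p = 1.47e-11), and 8 of 14 mast cell, basophil and eosinophil genes, with 0 higher (8 and 0 adjusted over the list alone; list adjusted p = 9.05e-09). T lineage genes were higher in 14 and lower in 0 of 27 cases (14 and 0 adjusted over the list alone; list adjusted p = 1.06e-07), a call lost with an estimated correlation (adjusted p = 0.0906 with an estimated correlation), and late thymocyte genes in 6 and 0 of 15 (6 and 1 adjusted over the list alone; list adjusted p = 0.0139), also lost (adjusted p = 0.0908 with an estimated correlation). The Notch target list passed narrowly (list adjusted p = 0.0487) and was lost with an estimated correlation (adjusted p = 0.362 with an estimated correlation) and without GMP replicate 1, GMP replicate 3 or CLP replicate 2 (0.0574, 0.0616 and 0.0679), without dim genes (0.111) and with the 3' to 5' covariate (0.178; range over alternatives 0.00864 to 0.362). Over all genes, 3043 were higher and 2110 lower, 5153 in all. The populations lay in different spike-in clusters, and with the cluster as a random block 1247 genes passed. The Gapdh 3' signal exceeded the 5' signal by 3.33 ± 0.24 in CLP and 1.95 ± 0.10 in GMP, without overlap.

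DNA methylation genes are given for every population because the series title concerns the methylome. Dnmt3b, a de novo DNA methyltransferase, was at 12.31 ± 0.07 in MPPFL- (SD, n = 5) by the probe set used, and at 11.60 ± 0.66 in MPPFL+, 9.49 ± 0.34 in CMP and 7.91 ± 0.14 in GMP (SD, n = 3). It fell by 2.11 on the log2 scale from MPPFL+ to CMP (SE 0.33, adjusted p = 0.000104) and fell by 1.58 on the log2 scale from CMP to GMP (SE 0.33, adjusted p = 0.00165). In CLP it was at 10.81 ± 0.49, higher than in GMP by 2.90 (SE 0.33, adjusted p = 1.14e-06), and from DN2 to DN3 it fell by 1.26 on the log2 scale (SE 0.33, adjusted p = 0.00585). Its other probe set moved the same way in these comparisons except from MPPFL+ to CMP, where it did not pass (-0.32, SE 0.20, adjusted p = 0.332 over all probe sets), and ranked the populations differently, with 8.73 ± 0.25 in MPPFL-, 9.64 ± 0.10 in MPPFL+ and 11.18 ± 0.40 in DN1. Dnmt1, which copies methylation after replication, and Uhrf1, which recruits it, were at 13.44 ± 0.18 and 13.04 ± 0.23 in CLP and at 11.66 ± 0.68 and 10.86 ± 0.73 in DN1. Between these 2 populations Dnmt1 fell by 1.78 on the log2 scale (SE 0.28, adjusted p = 8.01e-05) and Uhrf1 fell by 2.18 on the log2 scale (SE 0.31, adjusted p = 2.84e-05). The other probe set of Uhrf1 did not pass here (-1.02, SE 0.49, adjusted p = 0.162 over all probe sets). From DN2 to DN3, Dnmt1 rose by 1.05 (SE 0.28, adjusted p = 0.00695), Uhrf1 by 2.23 (SE 0.31, adjusted p = 1.47e-05), and Tet1, an enzyme that oxidises methylated cytosine, by 2.60 (SE 0.51, adjusted p = 0.000485). All comparisons tested in this paragraph are between populations of different spike-in clusters. The cluster as a block was not run for named genes, so population and cluster cannot be told apart for these changes. The same holds for the enzymes below, apart from MPPFL+ with MPPFL- and DN2 with DN1.

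Uhrf1 was also higher in MPPFL+ than in MPPFL- by 1.61 (SE 0.28, adjusted p = 0.000446), but not with the mean of its probe sets (0.70, adjusted p = 0.135; range over alternatives 3.21e-05 to 0.135), and MPPFL- replicate 1 stood at 11.88. Dnmt3a, the other main de novo methyltransferase, fell by 1.56 on the log2 scale from MPPFL+ to CMP (SE 0.28, adjusted p = 0.00036) and was 1.93 higher in CLP than in GMP (SE 0.28, adjusted p = 2.15e-05). These directions turned with the mean of its probe sets, to 0.53 and -0.10, and 3 of its 4 other probe sets rose in CMP. From CLP to DN1 the Dnmt3a probe set used did not pass (-0.30). Of the 4 others, 3 rose, by 5.525, 2.26 and 0.91 (adjusted p = 2.83e-07, 1.63e-07 and 0.00372 over all probe sets), and 1 changed by 0.01. In MPPFL+ with MPPFL- the probe set used changed by -0.02. Of the others, 2 passed at -1.63 and -2.235 (adjusted p = 3.39e-06 and 0.00212 over all probe sets) and 2 did not pass. Tet2 rose by 1.30 in CMP (SE 0.26, adjusted p = 0.000839) and fell by 1.28 on the log2 scale from DN1 to DN2 (SE 0.26, adjusted p = 0.00278). Its other probe set passed in neither (-0.23 and -0.83, adjusted p = 0.772 and 0.0856 over all probe sets). In MPPFL+ with MPPFL- its 2 probe sets passed in opposite directions (-1.08 and 0.99, adjusted p = 0.0025 and 0.0068 over all probe sets). Its rise of 1.35 from CLP to DN1 (SE 0.26, adjusted p = 0.000447) turned to -0.33 with the mean of its probe sets, the other of which fell. Dnmt3l was at the lowest value in every population, and Tet3 near it, at 2.47 in MPPFL+ and 3.17 in CMP. Over 20 measured genes of the DNA methylation list and 8 comparisons, 41 of 160 pairs passed, 23 higher and 18 lower, and the list as a whole passed in none of the comparisons, with 4 genes higher and 6 lower in DN3 against DN2.

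**Figure D5:**
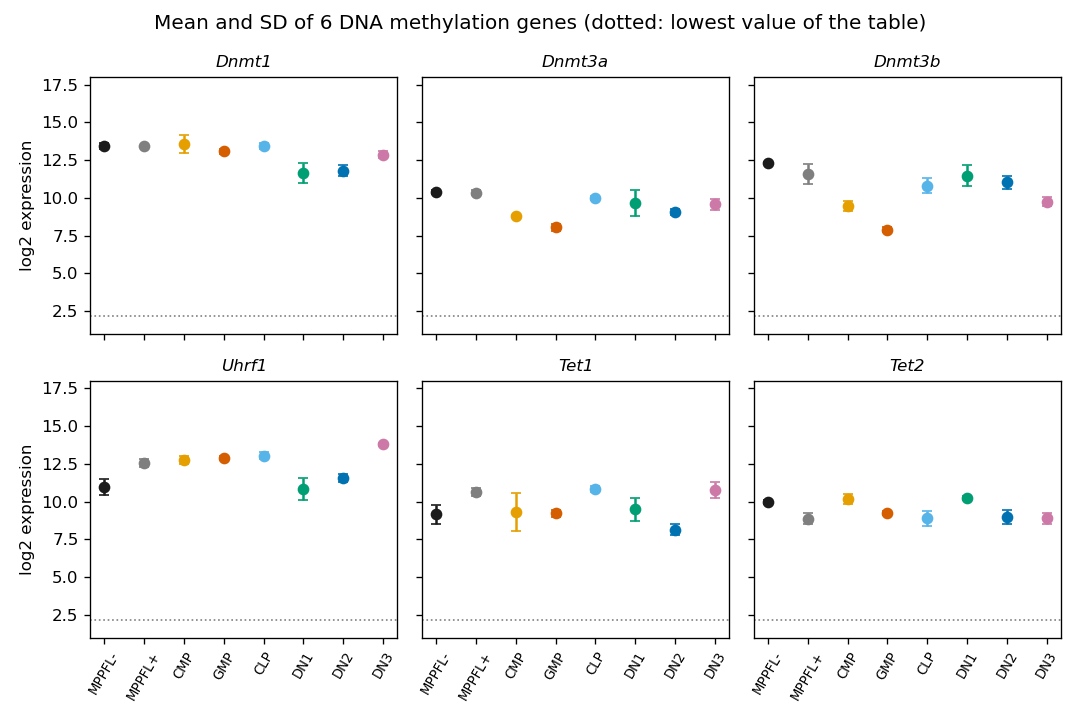
Mean log2 expression of 6 DNA methylation genes in the 8 populations, with bars of 1 SD (n = 5 in MPPFL-, n = 3 elsewhere) and a dotted line at the lowest value of the table. By the probe sets used, Dnmt3b is at 12.31 in MPPFL- and 7.91 in GMP, where its other probe set is at 8.73 and 8.02, and Dnmt1 and Uhrf1 are at 11.66 and 10.86 in DN1. Dnmt3a is at 9.98 in CLP and 9.68 in DN1, where 1 of its other probe sets is at 5.33 and 10.85.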

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

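The tests of spike-in clusters, of Xist and Y-linked genes, of the stress list across clusters, and of the share of DN2 RNA were chosen after the result was seen; the others were written down before.

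In MPPFL-, the only population with over 3 arrays, 1 array lay far from the others for 4 of 54 named genes tested (7.41%), where chance gives about 1 in 20. Ccr9 was at 3.09 on replicate 4, against 2.33 to 2.53 on the others. Replicate 1 stood apart for Cpa3 at 9.651 (others 10.97 to 11.09), Gp1bb at 3.31 (others 6.02 to 7.04) and Uhrf1 at 11.88 (others 10.58 to 10.83).

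A signal was also present in control probe sets that no comparison uses. The mean of the poly-A spike-in controls was 4.595 in MPPFL-, 4.48 in MPPFL+, 4.42 in CLP, 8.048 in GMP, 9.862 in CMP and 12.092 in DN3. In DN1 and DN2 it was 2.56 and 2.54, near the floor.

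Probe sets of a gene that passed the test in opposite directions were common in some comparisons. They made up 23.94% of 940 genes with at least 2 passing probe sets in MPPFL+ with MPPFL- and 29.1% of 1784 in DN1 with CLP, but 0% of 277 in CLP with MPPFL+. Processing that differs between spike-in clusters cannot be the whole cause, since MPPFL+ and MPPFL- share a cluster, though the lowest share across clusters, 8.369% in GMP with CMP, was above the 0% and 2.03% of CLP with MPPFL+ and DN2 with DN1, so that it may contribute there. With the Gapdh 3' to 5' difference as a covariate the shares were 23.52% and 30.24%. Its means were close in DN1 and CLP (3.38 and 3.33), so the covariate could hardly change that share. In MPPFL+ with MPPFL- the Gapdh difference changed the share little. The actin difference, which separated MPPFL+ from MPPFL- without overlap, was not put in the fit, so 3' to 5' signal stays open as a cause. Probe sets that can match several transcripts are argued against, because without those the shares were 30.33% and 37.76%. Use of different transcript ends by these populations also stays open and was not tested.

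Xist was high on thymocyte arrays labelled male. The highest Eif2s3y level on the 2 arrays with the most Xist was 2.616, against at least 11.28 on each of the 22 arrays with little Xist, which is consistent with female mice among the donors of these arrays. Cross-hybridisation of 1 probe set is argued against, since 3 Xist probe sets were higher on the arrays that lack Y-linked signal than on any array with little Xist. An array exchanged with another population is argued against, since 6 of 6 DN1 and DN2 arrays were nearest to their own population. DN1 replicate 1, with Xist at 12.21 and Eif2s3y at 12.76, could hold RNA of both sexes, a hypothesis for which no further test was run.

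Immediate early and stress genes were high in DN1 (list mean 11.64), DN2 (9.97) and CMP (9.71), and on DN3 replicate 3, which exceeded the other DN3 arrays by 1.88. The Gapdh 3' to 5' difference had close means in DN1 (3.38 ± 1.52) and CLP (3.33 ± 0.24, SD, n = 3). With it as a covariate the median change of the list from CLP was 2.581, against 2.56 without. Means this close could hardly move that median, so the covariate decides nothing for DN1. Handling or processing of sets of arrays and a state of the cells cannot be told apart in DN1 and DN2, because 0 of their arrays lie outside their shared spike-in cluster. For DN3 replicate 3 the same holds: the CMP arrays of its cluster were at 9.62 and 10.01, and the lower exceeded the CMP array outside it by only 0.123, but 1 array outside decides nothing. DN2 cells in that sample are argued against as the cause, since the 7 raised stress genes needed a share of DN2 RNA of at least 7.95% (median 20.2%) and 14 genes abundant in DN2 allowed at most 3.45% (Mpo, median 0.81%). A smaller share stays open. In a test set beforehand on only 2 genes besides Mpo, 50% were raised, Hhex at 4.47 but not Ifitm1 at 2.55 (named after their values were seen). Among the 14 genes, Emilin2, Lyl1 and Siglecf also exceeded both other DN3 arrays by over 1 log2 unit, but most of the 14 did not.

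For the number of changed genes in MPPFL+ with MPPFL-, 1 of the 56 splits of the 8 arrays gave as many genes. It was the real one, with 2885 against at most 117 in another. The arrays of MPPFL+ and MPPFL- thus differ as sets, but the splits cannot say why. Mixed splits carry any difference between the sets into the spread, so the real split leads whatever its cause. The ribosomal RNA control signal also separated these sets without overlap. The labels do not say that replicates came from separate animals, so chance differences between samples are not excluded. The other comparisons allow 10 splits, too few for a share under 0.05. The real and highest other counts were 4378 and 179 for CMP with MPPFL+, 3892 and 29 for GMP with CMP, 1190 and 24 for CLP with MPPFL+, 4890 and 12 for DN1 with CLP, 1475 and 99 for DN2 with DN1, 5652 and 10 for DN3 with DN2, and 5153 and 7 for CLP with GMP.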

How the results depend on the processing

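The spike-in cluster, 3' to 5' covariate, floor and Y-linked alternatives were chosen after the data were seen. Testing every probe set gave counts of 6760 for MPPFL+ with MPPFL-, 7233 for CMP with MPPFL+, 7287 for GMP with CMP, 1853 for CLP with MPPFL+, 10433 for DN1 with CLP, 2472 for DN2 with DN1, 10792 for DN3 with DN2 and 9384 for CLP with GMP, since a gene can then count more than once; 50.4% were higher in the first of these and 43.9% in DN1 with CLP. With only the 2 populations in the fit, the counts were 1139 for CMP with MPPFL+, 1591 for GMP with CMP, 596 for CLP with MPPFL+, 2886 for DN1 with CLP, 273 for DN2 with DN1 and 3694 for DN3 with DN2, while they rose to 2993 for MPPFL+ with MPPFL- and 5813 for CLP with GMP. With only the arrays of the shared spike-in cluster, DN2 with DN1 again gave 273. A further threshold of 2-fold, which can only lower a count, gave 1529 for MPPFL+ with MPPFL-, 2594 for CMP with MPPFL+, 2177 for GMP with CMP, 3083 for DN1 with CLP, 908 for DN2 with DN1, 3679 for DN3 with DN2 and 3261 for CLP with GMP. CLP against MPPFL- in place of MPPFL+, a different comparison, gave 4526. With the spike-in cluster as a random block, 636 genes passed for CMP with MPPFL+, 733 for GMP with CMP, 599 for DN1 with CLP, 1790 for DN3 with DN2 and 1247 for CLP with GMP, all of them comparisons across clusters. Without the 2 arrays lacking Y-linked signal, 798 passed for DN2 with DN1. Leaving out 1 array at a time gave 1898 (without MPPFL+ replicate 2) to 2862 for MPPFL+ with MPPFL-, and totals within 1.5 times of the reported ones in the other comparisons. Counts in 1 direction moved further, to 1887 higher for CMP with MPPFL+ and 2408 lower for GMP with CMP without CMP replicate 2, 1754 higher for CMP with MPPFL+ without CMP replicate 3, 481 higher for DN2 with DN1 without DN2 replicate 2, and 594 lower for MPPFL+ with MPPFL- without MPPFL+ replicate 2. The cause of these moves was not tested beyond what is said here.

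With replicate number as a block, 1813 genes passed for MPPFL+ with MPPFL-. Numbers 4 and 5 occur in MPPFL- alone, so those arrays no longer bear on this comparison and the lower count is no measure of pairing. Under the same block all 56 list calls held, as did 461 of 474 named genes and DNA methylation enzymes. Whether the numbers pair the samples is not settled. Deviations of same-numbered arrays from their population means correlated, across genes, between -0.439 and 0.438, and in 0 of the comparisons did all 3 pairs exceed 0.1. For replicate 1 the correlation was 0.257 in MPPFL+ with MPPFL- and 0.438 in CLP with MPPFL+, while replicates 2 and 3 gave negative values in both. Replicate 1 of MPPFL-, MPPFL+ and CLP lay in 1 spike-in subcluster, with MPPFL+ replicate 2.

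Of the 56 list calls, 31 held with an estimated correlation, 53 with quantile normalization, 54 with the mean of all probe sets, 53 without dim genes and 52 with the 3' to 5' covariate. Of the named genes and DNA methylation enzymes, 6 turned with the mean of all probe sets of a gene: Dnmt3a to 0.526 in CMP with MPPFL+, 1.683 in DN1 with CLP and -0.099 in CLP with GMP, Tet2 to -0.328 in DN1 with CLP and 0.655 in DN3 with DN2, and Uhrf1 to -0.933 in CLP with GMP; the cause was not tested. In 447 of 474 cases direction and side of the threshold held under that setting, as they did in 469 with quantile normalization, 460 with the covariate and all 474 with trend and robust variance. The nearest array was of the same population in 26 of 26 cases under every similarity alternative. Signal over background limits genes near the floor, where no fold change is given between populations that both lie on it.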

Other observations

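Single genes of the NK and innate lymphoid list changed where the list as a whole did not pass. Of its 18 genes, 2 rose and 3 fell in DN2 with DN1 (list adjusted p = 0.553), 2 rose and 5 fell in DN3 with DN2 (list adjusted p = 0.237), and 3 rose and 0 fell in CLP with MPPFL+ (list adjusted p = 0.0557). Zbtb16, a transcription factor of innate-like lymphocytes, was at 8.42 ± 0.43 in DN2 (SD, n = 3), higher than in DN1 by 5.65 (SE 0.45, adjusted p = 6.44e-08), and fell by 5.21 on the log2 scale from DN2 to DN3 (SE 0.45, adjusted p = 2.79e-08). It was also high in CMP, at 7.81 ± 0.55, a rise of 5.03 from MPPFL+ (SE 0.45, adjusted p = 1.43e-07). Gzma, a granule protease of killer cells, rose by 5.54 from DN1 to DN2 (SE 0.75, adjusted p = 5.08e-05). Klrd1, a natural killer cell receptor, rose by 5.17 from MPPFL+ to CLP (SE 0.41, adjusted p = 2.94e-08) and fell by 6.42 on the log2 scale from DN1 to DN2 (SE 0.41, adjusted p = 2.36e-09).

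Of 20 dendritic cell and macrophage genes, 3 rose and 2 fell in CLP with MPPFL+, and the list did not pass (list adjusted p = 0.444). Itgax, the integrin chain CD11c, rose by 4.19 (SE 0.29, adjusted p = 5.71e-09), and Siglech, a receptor of plasmacytoid dendritic cells, was at the floor on all MPPFL+ arrays and at least 8.50-fold higher in CLP (adjusted p = 1.09e-08). In DN3, Epcam, an adhesion protein of epithelium, was at 10.61 ± 0.06 and higher than in DN2 by 7.76 (SE 0.28, adjusted p = 5.03e-14), while 1 of the other 17 genes of the stroma list rose and 1 fell. These were Psmb11, by 1.04-fold, and Col3a1, by 1.25-fold, both next to the floor, where levels carry little information. Counts of list members include such small changes. Spib, a transcription factor of B cells and plasmacytoid dendritic cells, rose by 7.18 from DN2 to DN3 (SE 0.34, adjusted p = 3.31e-12). In that comparison 0 of 20 dendritic cell and macrophage genes rose and 4 fell, and 8 of 23 B lineage genes rose and 3 fell. Neither list passed (list adjusted p = 0.0784 and 0.0512).

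Ribosomal RNA control signal, which no comparison used, was lower on the DN1 and DN2 arrays than on the others. Its mean was 9.67 ± 1.87 in DN1 and 7.92 ± 0.35 in DN2 (SD, n = 3), against 12.81 ± 0.29 in MPPFL+ and 14.15 ± 0.15 in MPPFL- (SD, n = 5). The Gapdh 3' signal exceeded the 5' signal by 1.95 ± 0.10 in GMP and 2.26 ± 0.35 in CMP, and by 3.07 ± 0.23 to 3.65 ± 0.45 in the other populations.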
